A study of Mus musculus with 8 samples.

How the data were processed

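The data set holds 8 arrays of mouse J1 embryonic stem cells, in 4 groups of 2 arrays: a control hairpin (shControl), 2 hairpins against Fbxl19 (shRNA1 and shRNA2) and cells on day 4 of differentiation. Groups and replicate numbers were taken from the sample titles. A free-text label of the knockdown samples counts upward from Fbxl19 to other Fbxl genes across the samples, while titles and source names give Fbxl19 throughout, and the latter were followed. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. They also do not say how differentiation was carried out, or whether the day 4 cells carried a hairpin.

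The authors deposited log2 expression values, 1 per probe set, made with RMA per the submitters' processing notes (background correction, quantile normalization and summary of a probe set's probes). The RMA version, and whether the 8 arrays were normalized together, are not given in the sources used here, and the quartiles of shControl replicate 2 (3.79, 5.81 and 8.18) lay outside the range of the other 7 arrays. The labels name a Cy3 label, whereas the design text names an Affymetrix Mouse 430A 2.0 array. The values ran on each array from about 2 to 14. The table held 22690 probe sets, 64 of them array controls. Of these, 20393 had 1 gene symbol in the platform annotation, 691 had several and 1606 were unnamed. Symbols were matched by gene identifier for 20364 probe sets to a RefSeq gene table of assembly GRCm38.p6, used for names and for the chromosome a gene lies on. No build is named for the array, so no coordinates are given.

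For each gene with a probe set of its own, the probe set with the highest mean over the 8 arrays was kept, giving 12394 genes. A linear model with a mean for each of the 4 groups was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), leaving 4 residual degrees of freedom. Tested were the mean of both hairpins against shControl, each hairpin against shControl, shRNA2 against shRNA1, and day 4 against shControl. Errors of log2 fold changes are the moderated standard errors (SE) of that model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fixed gene lists, 29 in number, were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, with adjustment over the lists of a comparison. The fry test asks whether the genes of a list move on balance in 1 direction, without reference to other genes.

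The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 10 genes with the largest rise and 10 with the largest fall among called genes whose arrays did not overlap between the sides compared (5 and 5 for single hairpins and for the difference between them). Where no gene was called, it took the 5 and 5 with the smallest p. It also took up to 4 members of each list with the largest change, and the 5 and 5 genes with the largest smaller change under both hairpins. Predicted genes without a proper symbol and probe sets with several genes or none were counted and not named. Fbxl19 itself was to be reported first, but no probe set was annotated to it, so its level was not analysed here.

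The model was tested on simulated data, with 200 of the 12394 genes changed. For the mean of both hairpins it recovered 96.7% of genes changed 2-fold, and for shRNA1 against shControl 90.95%. On average 14.7 and 13.2 unchanged genes were called as well. The simulated arrays were independent and had the same spread in every group, whereas the shControl arrays differed more than those of either hairpin. These rates may therefore not hold for the data. Agreement between comparisons that share the control arrays was set against 100 simulations of unchanged groups, again with the same spread in every group. The alternatives tried were every probe set tested, the mean of a gene's probe sets, leaving out the dimmest 30% of genes, eBayes with trend and robust settings, a fit of the compared groups alone, array weights, repeated quantile normalization, centring of arrays, a minimum change of 1.5-fold, the replicate number as a block, and leaving out each array in turn. Arrays have no read depth, and their number limits the precision.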

Results

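Gene expression was measured on Affymetrix microarrays in mouse J1 embryonic stem cells, a line grown with leukemia inhibitory factor (LIF), after knockdown of Fbxl19. Fbxl19 encodes an F-box protein with a CXXC zinc finger, a domain that binds unmethylated CpG DNA. There were 4 groups of 2 arrays: a control hairpin, Fbxl19 shRNA1, Fbxl19 shRNA2, and cells on day 4 of differentiation. The series asked how gene expression in stem cells changes when Fbxl19 is reduced. No probe set was annotated to Fbxl19, so the degree of knockdown was not measured here and the hairpin labels were not checked against their target.

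Arrays of a group correlated with Pearson's r across probe sets of 0.997 for shRNA1, 0.996 for shRNA2, 0.993 for shControl and 0.989 for day 4. The shControl arrays differed from each other by more than the arrays of either hairpin. The SD of the difference between partners across genes was 0.31 on the log2 scale for shControl, against 0.20 for shRNA1 and 0.22 for shRNA2. For day 4 it was the largest, 0.41. The day 4 arrays enter comparisons among the undifferentiated groups only through the estimate of spread, which all groups share. Replicate 1 of shControl was closer to replicate 1 of shRNA2 (r = 0.996) than to its own partner. Replicate 2 of shControl also stood apart in its distribution, with quartiles of 3.79, 5.81 and 8.18, where the other 7 arrays had lower quartiles of 3.84 to 3.90, medians of 5.70 to 5.76 and upper quartiles of 8.04 to 8.08. A sign of RNA quality, the 3'-to-5' difference of the actin control probe sets, was 0.60 and 0.54 on the shControl arrays, 0.70 to 0.76 on the 4 knockdown arrays and 0.73 and 0.65 on day 4, so it separated the control arrays from all others. That of Gapdh overlapped, with 0.17 and 0.26 in shControl, 0.18 to 0.27 in knockdown and 0.26 and 0.20 on day 4.

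With both hairpins averaged, 7 genes rose and 2 fell against shControl among 12394 genes. Usp17la, a deubiquitinase gene of a multi-copy family, rose by 2.49 ± 0.17 on the log2 scale (SE, 4 knockdown against 2 control arrays; limma adjusted p = 0.00207). Its control mean, 3.49, lay below the lower quartile of every array, and no measure of background is given, so no fold is stated. Its probes may also read near-identical copies. Dcxr, which encodes dicarbonyl and L-xylulose reductase, rose by 1.42 ± 0.13 (adjusted p = 0.0107), and Ephx1, the microsomal epoxide hydrolase, rose by 1.11 ± 0.12 (adjusted p = 0.0152). The p53-induced genes Ccng1 and Btg2 rose by 1.18 ± 0.12 (2.27-fold) and 0.95 ± 0.12, with adjusted p of 0.0122 and 0.0462. Fgf18, a fibroblast growth factor, changed by -1.79 ± 0.23 (adjusted p = 0.0462), and Dmrt1, a transcription factor of the germ line, by -0.93 ± 0.11 (adjusted p = 0.0350).

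Plxdc2 rose by 0.85 ± 0.11 (adjusted p = 0.0474). AF067061, measured by 1 probe set, was called with a mean change of 1.62, but its shRNA2 arrays overlapped the controls and the rise lay in shRNA1. The arrays of the other 8 genes did not overlap between knockdown and control. Chance gives this for 13.3% of unselected genes, but calling genes by p selects for it, so it is no separate support. At an unadjusted p under 0.05 there were 1044 genes, where 619.7 would be expected by chance. With only the compared groups in the fit, so that the day 4 arrays did not enter the estimate of spread, 54 genes were called. The count of 9 thus depended on that shared estimate, and also on single arrays. It was 0 without either shControl array, 2 and 4 without shRNA1 replicate 1 and replicate 2, 1 and 2 without shRNA2 replicate 1 and replicate 2, and 54 without either day 4 array.

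**Figure D1:**
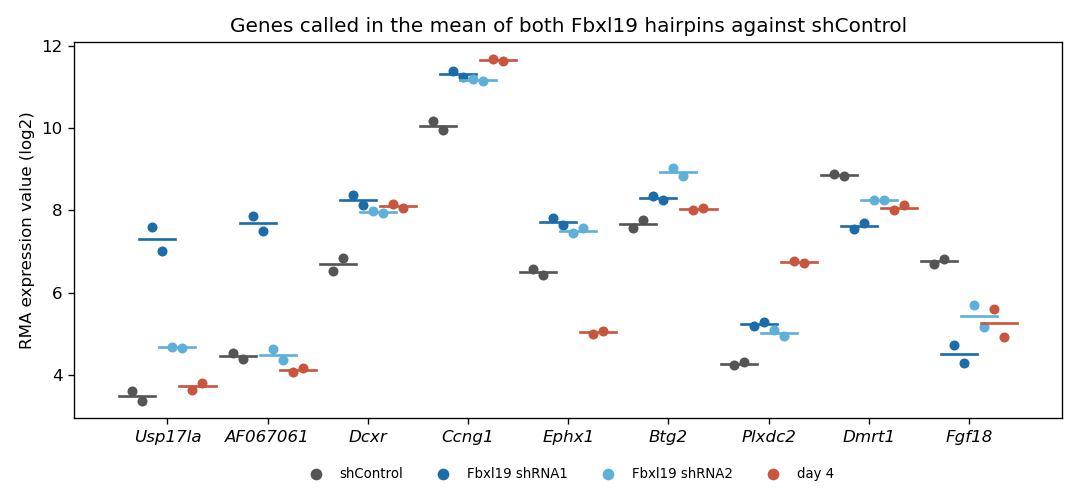
RMA expression values on the log2 scale (vertical axis) of the 9 genes called in the mean of both hairpins; each point is 1 array and each bar the mean of a group's 2 arrays. Usp17la and AF067061 stand higher with shRNA1 than with shRNA2, while Dcxr, Ccng1, Ephx1 and Plxdc2 lie at similar levels with both hairpins.

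Of the 29 gene lists, 5 were called in the mean of both hairpins by camera at the preset correlation, 4 of them higher and 1 lower. None was called with an estimated correlation. The actin 3'-to-5' difference was 0.54 and 0.60 in shControl and 0.70 to 0.76 on the knockdown arrays. It separated these groups, as did the array medians of the p53, epithelial and cholesterol lists. Relative to the shControl mean, the two-cell medians with shRNA2 (0.083 and 0.078) lay within the shControl range (-0.10 to 0.10). The glycolysis medians on replicate 1 of each hairpin (-0.07 and 0.06) also lay within the shControl range (-0.20 to 0.20). The list of p53 targets had a median change of 0.34 over 25 measured genes, of which 21 lay above 0 (camera adjusted p = 5.25e-12, and adjusted p = 0.222 with an estimated correlation). Its members Ccng1 and Btg2 rose, 2 genes when adjusted over all genes and 13 when adjusted over the list alone. Pmaip1, which encodes the pro-apoptotic protein Noxa, had 1.18 ± 0.17 (adjusted p = 0.0708), and Plk2 had 1.00 ± 0.23 (adjusted p = 0.248). The list's median was 0.32 with shRNA1 and 0.50 with shRNA2.

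Genes of the two-cell stage embryo had a median of 0.20 over 10 genes (camera adjusted p = 0.000306, and adjusted p = 0.222 with an estimated correlation). Usp17la rose, and 4 genes passed when adjusted over the list alone, among them Arg2 with 0.92 ± 0.21 and Zfp352 with 0.77 ± 0.15, neither of which passed over all genes; the control mean of Zfp352, 3.69, lay below the lower quartile of every array. The list was called with shRNA1 (median 0.27, camera adjusted p = 1.08e-05, and adjusted p = 0.356 with an estimated correlation) and not with shRNA2 (median 0.13, camera adjusted p = 0.327). With shRNA2, Arg2 had 0.10 ± 0.24 (-0.09 without shRNA2 replicate 1 and 0.29 without shRNA2 replicate 2). Zfp352 had 0.17 ± 0.18 with shRNA2 (0.30 and 0.037 without shRNA2 replicate 1 and replicate 2, and 0.024 with the mean of its probe sets). With the mean of a gene's probe sets the median was 0.10, and with the dim genes left out 3 members remained and the list was not tested. Epithelial markers had a median of 0.19 over 23 genes (camera adjusted p = 0.00218, and adjusted p = 0.222 with an estimated correlation). The desmosomal gene Dsp had 1.02 ± 0.25 (adjusted p = 0.283), and 0 members passed over all genes and 2 over the list alone. Without shControl replicate 1 the median was 0.12 and Dsp had 0.62, and with the mean of its probe sets Dsp had 0.60. The fry test did not call this list or the next (adjusted p = 0.125 for both). Cholesterol biosynthesis genes had a median of -0.23 over 19 genes, 3 of them above 0 (camera adjusted p = 0.000139, and adjusted p = 0.399 with an estimated correlation). Hsd17b7 had -0.57 ± 0.13 and Sc5d had -0.53 ± 0.15 (-0.28 with the mean of its probe sets); 3 members passed when adjusted over the list alone and 0 over all genes.

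Glycolysis and hypoxia genes had a median of 0.37 over 28 genes (camera adjusted p = 0.000139, and adjusted p = 0.870 with an estimated correlation). The estimated correlation between these genes was 0.628. Ddit4 had 1.77 ± 0.36 (adjusted p = 0.170) and Bnip3 had 1.64 ± 0.64 (adjusted p = 0.549; 0.76 and 2.52 without shControl replicate 1 and replicate 2), and 1 member passed when adjusted over the list alone. The call was lost with fry (adjusted p = 0.827) and without shControl replicate 1, where the median was 0.05 (adjusted p = 0.406). The median was 0.60 without shControl replicate 2, 0.18 without shRNA1 replicate 2 and 0.21 without shRNA2 replicate 2. The list's median differed within groups. Relative to the shControl mean it was -0.20 and 0.20 on the shControl arrays, -0.07 and 0.72 on the shRNA1 arrays, and 0.06 and 0.62 on the shRNA2 arrays, replicate 2 being the higher in each.

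The remaining 24 lists were not called by camera or fry, the smallest camera adjusted p among them being 0.0632, for trophoblast genes. They included the pluripotency list, with a median of 0.00 over 31 genes (adjusted p = 0.578). The machinery of H2B ubiquitination had a median of -0.02 over 16 genes (adjusted p = 0.578), in which Usp22, a deubiquitinase of the SAGA complex, had -0.58 ± 0.15 (adjusted p = 0.310). Polycomb complex genes had a median of -0.05 over 22 genes, and genes of Mediator and its kinase module -0.04 over 25 genes (adjusted p = 0.578 for both lists). No member of these 4 lists was called.

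**Figure D2:**
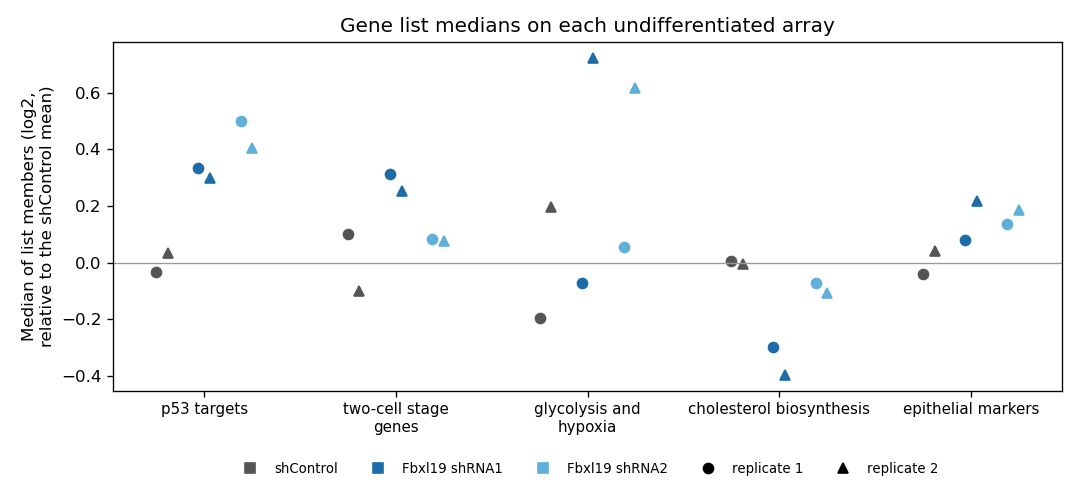
Median log2 value of the measured members of 5 gene lists on each undifferentiated array, relative to the mean of the shControl arrays (vertical axis); colours are groups, circles replicate 1 and triangles replicate 2. The p53 list lies between 0.30 and 0.50 on the 4 knockdown arrays, and the glycolysis and hypoxia list separates replicate 1 from replicate 2.

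With shRNA1 alone, 21 genes rose and 9 fell. Usp17la rose by 3.81 ± 0.20 (adjusted p = 9.29e-05), and AF067061 by 3.22 ± 0.16. Arg2, the mitochondrial arginase, rose by 1.74 ± 0.24, Pmaip1 by 1.68 ± 0.20 and Dcxr by 1.57 ± 0.16. Fgf18 changed by -2.25 ± 0.26, the nuclear pore gene Nup210 by -1.51 ± 0.18, the elongin A gene Eloa by -1.43 ± 0.16, Mcrs1 by -1.36 ± 0.14 and Dmrt1 by -1.24 ± 0.13. The adjusted p of these genes other than Usp17la was at most 0.0276, that of Arg2. With the mean of its probe sets Eloa had -0.92 and was not called (adjusted p = 0.0555). The count of 30 was 2 without either shControl array, 3 without either shRNA1 array, 18 without either shRNA2 array and 113 without either day 4 array.

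With shRNA2 alone, limma called 0 genes, with 632 at an unadjusted p under 0.05. The genes with the smallest p, none of which passed, included Btg2 with 1.27 ± 0.14, Dcxr with 1.27 ± 0.16 and Ccng1 with 1.11 ± 0.14 (adjusted p = 0.0879 for the 3 genes), Ephx1 with 1.00 ± 0.13 and Neurod1 with 1.55 ± 0.23. On the lower side were Oxsr1 with -1.09 ± 0.14, the cyclin gene Ccnd2 with -1.15 ± 0.16, Enoph1 with -0.98 ± 0.16, Trappc10 with -0.997 ± 0.168 and Uhmk1 with -1.49 ± 0.26 (-0.75 with the mean of its probe sets). The count was 12 without either day 4 array, and 40 with shRNA2 and shControl alone in the fit.

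Because shRNA2 alone had 0 called genes, 0 genes were called with both hairpins by limma. The count was 7 without either day 4 array, and 18 with only the compared groups in the fit. At an unadjusted p under 0.05, 288 genes moved in the same direction with both, 182 higher and 106 lower. Simulated unchanged groups of independent arrays against the same controls gave 137.3 on average, and independent lists would give 30.9. Across genes, which are not independent replicates, the changes with the 2 hairpins correlated with Pearson's r = 0.628 (Spearman's rho = 0.630), against 0.500 in the simulation. Their covariance was 0.0349 against a simulated 0.0174. The simulation gave a gene the same spread in every group, whereas the shControl arrays differed by more than those of either hairpin. The simulated agreement may therefore be too low. The pair of control arrays was not split between the comparisons, and part or all of the excess may come from the shared controls. At that unadjusted threshold, the largest changes under both hairpins were those of Ddit4 (1.61 and 1.92 with shRNA1 and shRNA2), Dcxr (1.57 and 1.27), Sdc4 (1.44 and 1.22), Krt7 (1.40 and 1.21) and Usp17la (3.81 and 1.17). On the lower side were Fgf18 (-2.25 and -1.33), Msc (-1.50 and -1.09), Plagl1 (-1.67 and -0.94), Epop (-1.07 and -0.93) and Ccnd2 (-0.80 and -1.15). The control means of Krt7 (3.48) and Usp17la lay below the lower quartile of every array, so the size of their changes is uncertain. With the mean of its probe sets Plagl1 had -0.87 and -0.43, and without shRNA1 replicate 2 Ddit4 had 1.04 with shRNA1.

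Between the hairpins, 4 genes were higher and 9 lower with shRNA2 than with shRNA1. Lower with shRNA2 were AF067061, by -3.20 ± 0.16 (adjusted p = 0.000187), Usp17la, by -2.64 ± 0.20 (adjusted p = 0.00219), Pof1b, by -1.66 ± 0.17 (to a mean of 3.50, below the lower quartile of every array), Acss1, by -1.62 ± 0.18, and Trappc10, by -1.25 ± 0.17. Higher with shRNA2 were Eloa by 1.43 ± 0.16, Mcrs1 by 1.29 ± 0.14, Calml4 by 1.29 ± 0.17 and Cgref1 by 1.05 ± 0.13. The largest adjusted p among these 9 genes was 0.0399. The other probe sets of Eloa gave differences of 0.55 and 0.22, and those of Acss1 -0.33 and -0.38; with the mean of a gene's probe sets, neither Eloa (0.73) nor Acss1 (-0.78) was called. Of the lists, genes of the two-cell stage were lower with shRNA2, with a median of -0.28 (camera adjusted p = 4.47e-07, and adjusted p = 0.224 with an estimated correlation). Of its 10 members, 1, Usp17la, was called between the hairpins. The p53 targets (0.19), the FGF and ERK response (0.18) and cholesterol biosynthesis (0.16) had higher medians with shRNA2, with camera adjusted p of 0.00821, 0.00234 and 0.0110. With an estimated correlation their adjusted p were 0.705, 0.233 and 0.705, and none of the 3 was called with fry or with the dim genes left out. The p53 list was not called without shRNA1 replicate 2 (0.16) or shRNA2 replicate 1 (0.14) and had 0.33 without shRNA1 replicate 1. The cholesterol list was not called without those same 2 arrays (0.17 and 0.14) or after repeated quantile normalization. With the mean of a gene's probe sets the medians of the p53, FGF and ERK, and cholesterol lists were 0.12, 0.11 and 0.09, the last not called. The FGF and ERK list had 0.28 without shRNA1 replicate 2 and 0.27 without shRNA2 replicate 2. The count of 13 genes was 4 without either shControl array, 2 and 3 without shRNA1 replicate 1 and replicate 2, 2 without either shRNA2 array, and 37 without either day 4 array.

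On day 4 of differentiation, 951 genes were higher and 1082 lower than in shControl, 16.4% of the genes tested, of which 473 and 405 changed at least 2-fold. Which direction had more genes depended on the scaling, with 1127 higher and 932 lower after centring of the arrays and 1082 higher and 1067 lower after repeated quantile normalization. Among the genes with the largest falls, Socs3, a feedback inhibitor induced by LIF through STAT3, changed by -4.75 ± 0.26 (SE, 2 against 2 arrays), and Klf4, a transcription factor of naive pluripotency, by -4.55 ± 0.37. The homeobox gene Gbx2 changed by -4.12 ± 0.16 and Morc1 by -3.85 ± 0.15. Inhbb, an inhibin and activin subunit gene, changed by -6.26 ± 0.21 to a day 4 mean of 3.52, below the lower quartile of every array, and its other probe set gave -0.72 (mean of both -3.49).

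The iron exporter gene Slc40a1 rose by 5.06 ± 0.28, and the smooth muscle gene Tagln by 4.66 ± 0.27. The interferon-inducible genes Gbp2b and Gbp2 rose by 5.02 ± 0.24 and 4.30 ± 0.19, and Psmb8, an immunoproteasome subunit gene, by 4.18 ± 0.43. Car4 rose by 4.65 ± 0.51, the insulin receptor substrate gene Irs1 by 4.35 ± 0.27, Sall2 by 4.14 ± 0.34, Tmem54 by 4.04 ± 0.31 and the protocadherin gene Pcdh8 by 3.99 ± 0.23. Also lower were Mras (-5.02 ± 0.19), Emp1 (-4.72 ± 0.29), Calml4 (-4.28 ± 0.17), Slc66a2 (-4.03 ± 0.22, or -2.55 with the mean of its probe sets) and Pcolce (-3.88 ± 0.20). The largest adjusted p among these 20 genes was that of Car4, 0.000374. Of these 20 genes, 8 had a group mean below the lower quartile of every array (Inhbb and Emp1 on day 4, and Gbp2b, Gbp2, Psmb8, Sall2, Tmem54 and Pcdh8 in shControl), where background is not given and the size of the change is uncertain. The count of 2033 was 1103 without shControl replicate 2 (607 higher and 496 lower), and lay between 1578 and 2628 without any other array.

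Of the 29 lists, 7 were called on day 4 at the preset correlation, 5 higher and 2 lower, and none with an estimated correlation. The actin 3'-to-5' difference was also higher on day 4 (0.73 and 0.65) than in shControl (0.60 and 0.54). Of 31 pluripotency genes, 21 fell and 1 rose when adjusted over all genes, and 24 and 1 when adjusted over the list alone. The median was -1.42 (camera adjusted p = 6.19e-11, and adjusted p = 0.276 with an estimated correlation). Besides Socs3 and Klf4, Tcl1 changed by -3.83 ± 0.43 and Esrrb by -3.71 ± 0.63; Esrrb had -2.42 without day 4 replicate 2 and was not called without shControl replicate 2 (-3.60). Of 15 genes of formative and primed pluripotency, 7 rose and 2 fell (8 and 2 over the list alone), with a median of 0.89 (camera adjusted p = 0.000235, and adjusted p = 0.529 with an estimated correlation). Pou3f1 rose by 3.53 ± 0.19, Cldn6 by 3.05 ± 0.19 and Zic2 by 2.65 ± 0.21. The list's median was 1.69 without day 4 replicate 1 and 0.51 without day 4 replicate 2.

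Of 23 epithelial markers, 14 rose and 2 fell (the same numbers over the list alone), with a median of 0.92 (camera adjusted p = 3.18e-08, and adjusted p = 0.105 with an estimated correlation). The tight junction gene Cldn7 rose by 3.98 ± 0.29, and the keratin genes Krt18 and Krt8 rose by 3.53 ± 0.24 and 2.83 ± 0.27. Of 15 genes responding to TGF-beta, Nodal and BMP, 7 rose and 0 fell (8 and 0 over the list alone), with a median of 0.59 (camera adjusted p = 0.000131, and adjusted p = 0.183 with an estimated correlation). Ccn1 and Ccn2 rose by 2.75 ± 0.33 and 2.74 ± 0.23, and Id2 by 2.50 ± 0.22. The median was 0.93 without day 4 replicate 2. Of 25 imprinted genes, 9 rose and 0 fell (13 and 0 over the list alone), with a median of 0.52 (camera adjusted p = 0.000993, and adjusted p = 0.183 with an estimated correlation), including Grb10 by 1.44 ± 0.23 (0.68 with the mean of its probe sets) and Peg3 by 1.39 ± 0.18.

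Of 25 p53 targets, 11 rose and 2 fell on day 4 (14 and 2 over the list alone), with a median of 0.50 (camera adjusted p = 0.000235, and adjusted p = 0.296 with an estimated correlation). Pmaip1 rose by 1.88 ± 0.20 and Ccng1 by 1.59 ± 0.14. Of 29 proliferation genes, 3 fell over all genes and 0 over the list alone, with a median of -0.35 (camera adjusted p = 0.00247, and adjusted p = 0.663 with an estimated correlation). Bub1b, a gene of the spindle checkpoint, changed by -0.73 ± 0.19 (adjusted p = 0.0307), a call lost on leaving out any 1 array other than day 4 replicate 2, with -0.83 and -0.62 without shControl replicate 1 and 2 and -0.46 without day 4 replicate 1. The proliferation list was not called without day 4 replicate 1 (median -0.17, adjusted p = 0.115) or with fry (adjusted p = 0.115), and had -0.53 without day 4 replicate 2. Lists of germ layer genes were not called by camera, while fry called neuroectoderm genes (median 0.22, fry adjusted p = 0.0463, against a camera adjusted p of 0.144). Fry also called trophoblast and germline genes (adjusted p = 0.0463 for both), the H3K4 and H3K79 methylation and Polycomb complexes (0.0350 for both) and housekeeping genes (0.00961), which camera did not. Primitive streak and mesendoderm genes had 4 higher and 1 lower of 19, Eomes rising by 2.70 ± 0.43. Neuroectoderm genes had 5 higher and 4 lower of 27, Sox11 rising by 2.58 ± 0.13, and Hox genes had 0 called of 31.

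**Figure D3:**
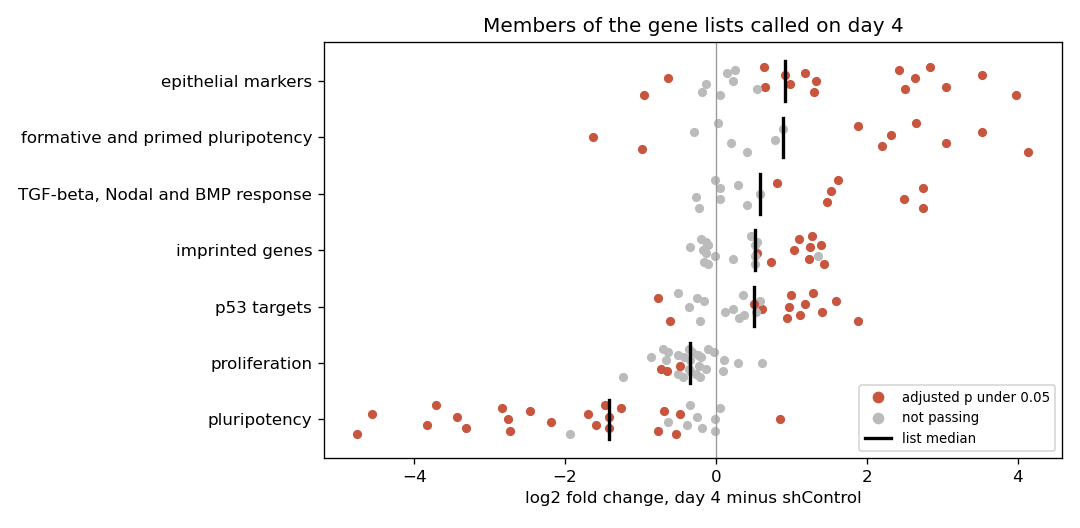
Log2 fold change of day 4 against shControl (horizontal axis) for each measured member of the 7 gene lists called on day 4; each point is a gene, coloured where its adjusted p was under 0.05, and the black bar is the list median. The pluripotency list has a median of -1.42, and epithelial markers one of 0.92.

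The changes on knockdown and on day 4 were compared across genes, which are not independent replicates. They correlated with Pearson's r = 0.193 and Spearman's rho = 0.306. Both lay below the 0.578 and 0.553 that shared controls gave in simulations of unchanged groups, a value that does not hold where effects differ in size. The covariance was 0.0254 against a simulated 0.0174. The simulation gave a gene the same spread in every group. The shControl arrays, which both comparisons share, differed from each other by more than those of either hairpin. The simulated covariance may therefore be too low, and its distance from the observed value was not taken as agreement. Of the 9 genes called on knockdown, 3 were higher in both comparisons, 2 lower in both and 1 opposite, where independent lists would give 0.537, 0.175 and 0.765. Dcxr, Ccng1 and Plxdc2 were higher in both, on day 4 by 1.43, 1.59 and 2.47. Fgf18 and Dmrt1 were lower in both, on day 4 by -1.50 and -0.80; the day 4 call of Fgf18 was lost without shControl replicate 2 (-1.44). Ephx1 rose on knockdown and had -1.47 on day 4. The controls were not split between the comparisons, and part or all of the excess may come from them. Without shControl replicate 1, Pearson's r was 0.359.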

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

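The tests of p53 targets, two-cell stage genes and glycolysis genes in this part were chosen after the results were seen.

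Differences between the hairpins were tested directly. They drew attention to 13 genes, among them AF067061 (-3.20 with shRNA2 minus shRNA1, log2), Usp17la (-2.64), Pof1b (-1.66), Acss1 (-1.62), Trappc10 (-1.25), Eloa (1.43), Mcrs1 (1.29), Calml4 (1.29) and Cgref1 (1.05). The lists that differed were two-cell stage genes (-0.28), p53 targets (0.19), the FGF and ERK response (0.18) and cholesterol biosynthesis (0.16), none of them with an estimated correlation (adjusted p = 0.224, 0.705, 0.233 and 0.705). Among the 1555 probe sets that are unnamed and not array controls, 65 were higher and 83 lower on day 4 than in shControl. These enter no comparison of genes in the report, only the alternative that tests every probe set.

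Genes of the two-cell stage had a lower median with shRNA2 than with shRNA1, with 1 of 10 members called and an adjusted p of 0.224 with an estimated correlation. Cross-reading within the Usp17l family stays open for the list as a whole. Without Usp17la the list had a camera p of 1.45e-05 (unadjusted p = 0.0108 with an estimated correlation). Its median of -0.25 ± 0.19 (bootstrap SE over genes) lay within 2 SE of 0. Arg2 and Zfp352, outside that family, rose with shRNA1 against shControl, by 1.74 ± 0.24 and 1.37 ± 0.18 (limma adjusted p = 0.0276 and 0.0219). Cross-reading in the family would not give these rises, but neither gene was called between the hairpins. The control mean of Zfp352 lay below the lower quartile of every array. The direction of the two-cell list's difference did not rest on a single aberrant array. Relative to the shControl mean, its median was 0.31 and 0.25 on the shRNA1 arrays and 0.083 and 0.078 on the shRNA2 arrays. The highest camera adjusted p without each of the 4 knockdown arrays was 8.82e-06. The 4 pairwise differences between arrays, shRNA1 minus shRNA2, had medians from 0.23 to 0.34. Each lay within 2 bootstrap SE of 0, a spread between genes, so the share of a single array in its size stays open. A larger effect of shRNA1 on every knockdown gene alike would also lower the p53 targets with shRNA2, but their median was higher with shRNA2 by 0.19 ± 0.08, a list not called without shRNA1 replicate 2 (0.16) or shRNA2 replicate 1 (0.14), with 0.33 without shRNA1 replicate 1. An off-target effect of shRNA1 and a different depth of knockdown were not tested, since Fbxl19 was not measured.

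The p53 targets had a higher median with both hairpins, with an adjusted p of 0.222 with an estimated correlation. If a single control array were the cause, the shift would vanish against the other, but the lower of the medians against each control array alone was 0.29 ± 0.09 (bootstrap SE). With each hairpin the lower median was 0.32 ± 0.12, against an off-target effect of only 1 hairpin. Both hairpins were set against the same control arrays, so a deviation shared by these would shift both medians alike. The bootstrap SE takes the genes of the list as independent, and may be too small. Partial differentiation that moved both lists in their day 4 proportion would lower the pluripotency list to about -0.96, and its median was 0.00057 ± 0.034. Partial differentiation in another proportion, or with shRNA1 alone, was not tested. With shRNA1, Otx2 rose by 1.38 ± 0.18 and Gbx2 changed by -1.17 ± 0.16 (limma adjusted p = 0.0219 and 0.0276). Both moved in their day 4 direction. Other genes called with shRNA1 did not, such as Cacna2d2 and Limch1. These rose by 1.34 ± 0.15 and 1.40 ± 0.18 and had lower means on day 4 than in shControl. Of the 9 genes called on knockdown, 3 were higher and 2 lower on day 4 as well, and 1 moved the opposite way. A difference in RNA quality stays open, as the actin 3'-to-5' difference separated the knockdown from the control arrays by 0.098 while that of Gapdh overlapped, and an effect of reduced Fbxl19 or a stress response to hairpins that the control hairpin lacks may also account for the shift and were not tested.

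Glycolysis and hypoxia genes were higher in replicate 2 than in replicate 1 of shControl (0.40), shRNA1 (0.60) and shRNA2 (0.54), against 0.05 on day 4. An equal shift of all genes would leave the list at the median of all genes, but the list exceeded it by at least 0.31 ± 0.14 (bootstrap SE over genes). That was the value in shControl, where all genes shifted by 0.08. The SE takes the genes as independent, although they varied together, so it is likely too small. An earlier bound for this test had left the question undecided. Scaling that depends on the signal level was not tested. The upper quartile of shControl was 8.04 in replicate 1 and 8.18 in replicate 2. A difference in RNA degradation stays open, since the actin 3'-to-5' difference was higher in replicate 2 in 1 of the 3 groups but moved by only -0.06, -0.004 and 0.03, less than the 0.08 between the day 4 arrays. No biological explanation was tested, as the design names none. A difference in cell density or oxygen between cultures is a candidate explanation that stays open.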

How the results depend on the processing

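None of the 84 called gene changes and no called list reversed its direction under the alternatives that gave a value. Of 37 uncalled gene changes, 1 did, Arg2 with shRNA2, from -0.0907 to 0.286 without single arrays. Of 1452 values of called gene changes, 1277 kept their call and 175 lost it, of 660 values of gene changes not called, 103 gained one, and of 286 values of 16 list calls, 252 kept it and 34 lost it. Of 4 uncalled knockdown lists near 0, 3 changed sign. The pluripotency list had -0.0256 with the mean of a gene's probe sets and from -0.0393 to 0.0742 without single arrays. The H2B ubiquitination list had 0.00369 with repeated quantile normalization, 0.00780 with centring and from -0.0605 to 0.0228 without single arrays, and the Mediator list 0.00580 with repeated quantile normalization and from -0.163 to 0.0285 without single arrays. Fbxl19 itself was not run, as no probe set was annotated to it. Unless stated, the cause of a change below was not tested.

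With an estimated correlation, 0 lists were called on knockdown, between hairpins and on day 4. With fry, the numbers were 2, 1 and 12. With the dim genes left out, 0 lists were called between hairpins, the two-cell list having 3 members left and not being tested, and the correlation of knockdown and day 4 changes was 0.168. Testing every probe set called 3210 on day 4, more features being tested, and gave a correlation of 0.228. Trend and robust settings called 48 genes with shRNA1, 2 with shRNA2 and 1 with both. Repeated quantile normalization called 51, 2 and 1, with a correlation of 0.171. Array weights called 5 genes on knockdown, 176 between hairpins and 1191 on day 4. With only the compared groups in the fit, 54 genes were called on knockdown, 113 with shRNA1, 40 with shRNA2, 18 with both and 1144 on day 4.

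With the replicate number as a block, 22 genes were called on knockdown, 49 with shRNA1 and 8 between hairpins; it called 0 genes with shRNA2 and 2307 on day 4. Deviations of same-numbered arrays correlated by 0.26 and 0.23 between shControl and each hairpin, by 0.50 between the hairpins, and from -0.08 to 0.07 with day 4, so the numbers were not taken as pairing. A replicate block without the day 4 arrays, chosen after seeing the data, called 241 genes on knockdown, 432 with shRNA1, 99 with shRNA2, 167 between hairpins and 60 with both.

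Leaving out each array in turn, where the lone array left is assumed to vary like the other groups, gave 0 to 54 genes on knockdown, 2 to 113 with shRNA1, 0 to 12 with shRNA2, 2 to 37 between hairpins, 0 to 7 with both and 1103 to 2628 on day 4. The correlation ranged from 0.137 to 0.359. Numbers of called lists ranged from 5 to 6 on knockdown, 3 to 5 between hairpins and 7 to 9 on day 4. Signal over background is not given, so the limit it sets for dim genes was not measured.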

Other observations

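The tests of STAT3 targets and of antigen presentation genes were set before the values of those genes were seen, on lists written after the day 4 results; the test by chromosome was chosen after its result was seen.

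Day 4 cells had less of several genes that act in or after LIF signalling. Icam1 fell by 2.85 ± 0.19 on the log2 scale, Stat3 itself fell by 2.25 ± 0.15, Ccnd3 fell by 1.92 ± 0.14, Pim3 fell by 1.29 ± 0.22 and Sgk1 fell by 1.25 ± 0.18 (SE, 2 against 2 arrays). The hypothesis was that STAT3 signalling is lower in the day 4 cells, as may follow from removal of LIF, which the labels do not state. Of 17 STAT3 targets outside the earlier results, 5 fell and 1, Cebpd, rose, and the median was -0.45 (camera p = 0.00131, and p = 0.0258 with an estimated correlation). The call of Pim3 was lost without shControl replicate 2 (-1.20), and that of Cebpd (0.99) on leaving out any 1 array other than day 4 replicate 2, with 0.78 and 1.20 without shControl replicate 1 and 2 and 0.55 without day 4 replicate 1; with the mean of its probe sets Cebpd had 0.56 and was not called.

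Of 12 measured genes of antigen presentation by MHC class I, 6 rose on day 4 and 0 fell. Erap1 rose by 3.21 ± 0.26, Tapbp by 1.75 ± 0.23, H2-K1 by 1.39 ± 0.27, Tap2 by 1.17 ± 0.30, H2-D1 by 0.97 ± 0.16 and Psme1 by 0.88 ± 0.18. The hypothesis was that the rise of Gbp2, Gbp2b and Psmb8 is part of a wider rise of this pathway. The median of the 12 genes was 0.75. With the mean of a gene's probe sets Tapbp had 1.11, H2-K1 0.79 and H2-D1 0.60. Without shControl replicate 1 the calls of H2-K1 (1.23), Psme1 (0.72) and Tap2 (1.45) were lost, and that of Tap2 also without shControl replicate 2 (0.89) and day 4 replicate 2 (0.70). Of the 12 genes, only H2-T24 (-0.11) lay below 0. The camera p was 1.34e-05 at the preset correlation and 0.141 with an estimated correlation, which was 0.480. Whether the list as a whole rose thus depends on how strongly its genes are taken to vary together. The fixed interferon response list was not called on day 4 (adjusted p = 0.212), and its member Oas1a changed by -2.37 ± 0.19.

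Gain or loss of a whole chromosome that sets groups apart, which stem cell cultures can acquire, was not seen. A change shared by all groups cancels in these comparisons, and a change in a small part of the cells may go unseen. Over 12378 genes on 20 chromosomes, the chromosome median farthest from 0 in any of the 5 comparisons was 0.063, for chromosome X on day 4.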
